A study of Mus musculus with 13 samples.

How the data were processed

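ChIP-seq of STAT5A, LSD1 and HDAC3 was measured in Ba/F3 mouse pro-B cells deprived of IL3 for 6 h, or deprived for 6 h and given 10 ng/mL IL3 for 30 min, with 2 biological replicates per protein and condition. The authors deposited 1 list of called regions for each of the 12 libraries and 1 for the pooled library of each of the 6 groups. Their processing notes name Trimmomatic 0.30, Bowtie2 2.1.0, Picard 1.92 and HOMER 4.8 and the mm10 assembly. The settings of the peak caller, its control and threshold, and any filter on problem regions are not given in the sources used here. An input library, a sample in neither condition, was not used here.

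Each region comes with a score that the authors deposited with it. The score is not defined in the sources used here, and in each list all low scores lie within 0.1 of a whole multiple of 1 step. Scores were used to rank regions and to compare medians within 1 list, and scores of separate lists are compared only as score steps, which also assume that 1 step is 1 read. The inverse of the step was read as relative depth, which holds if 1 step is 1 read. Region width is fixed within a list, between 123 and 235 bp. Regions off the assembled chromosomes were left out of all comparisons except the region counts per list.

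Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Regions were called shared when they overlapped by 1 bp or more. For each protein the 4 replicate lists were merged into 1 set of regions, and a region was called gained when it was in both replicates with IL3 and in neither without, and lost the other way round. In the comparisons over pooled lists, regions called with IL3 alone are those of the pooled list with IL3 that overlap none of the pooled list without IL3. Region numbers and shares per replicate were compared by a two-sided exact permutation test, whose smallest p is 0.333 for 2 against 2. Overlap and gene-end shares were compared with 1000 random placements on the same chromosome (one-sided, smallest p 0.000999), and median scores by a two-sided permutation test with 100000 resamples. Shares of regions and of genes were compared by a two-sided Fisher's exact test, and calls with IL3 alone against without IL3 alone by a two-sided exact binomial test. Regions are not independent replicates. Benjamini-Hochberg adjustment was done over 6 overlaps, 12 comparisons of region classes, 6 binomial tests, 11 replicate shares and 66 tests of gene lists, with a threshold of 0.05. Intervals on shares are 95% Wilson intervals, cover counting error only and do not cover the spread between libraries.

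The reference gives the bounds of 21887 protein-coding genes without strand, exons or sequence. A gene end is therefore either bound of a gene, promoters could not be told from 3 prime ends, and exons and introns are not known. Regions with their centre within 1 kb of a gene end stand for promoter regions, and genes with a region within 10 kb of an end stand for genes near a region. A single region is named by the gene it lies in or the gene with the nearest end, and that end can be more than 10 kb away. The planned comparisons of STAT motif content were not run, because no genome sequence was at hand.

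Before the data were examined, the groups, the comparisons, their tests, the alternatives and 11 gene lists were fixed, as was the rule for named genes. The lists are STAT5 targets, IL3 receptor and JAK-STAT components, immediate early genes, survival and apoptosis, cell cycle, B lineage, myeloid and mast cell, erythroid and T cell, LSD1 and HDAC3 complexes, tissue genes of other lineages as background, and ribosomal protein genes, 80 in all, found by symbol without the S6 kinases. The rule allows the genes nearest the 10 highest-scoring regions of each pooled list and region class, and up to 6 genes of each gene list with the highest-scoring region, up to 30 per protein. The text gives a part of these, chosen after their values were seen, and 1 item is not reported here. Socs1 and the genes named as having no region were chosen after their values were seen.

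Comparisons added after seeing the data were the change of LSD1 and HDAC3 at gained STAT5A regions, the STAT5A overlap of HDAC3 regions called in 1 condition, and placement of gene-end regions at other gene ends. The map around Pim1 and the exact permutation tests of differences between proteins were also added then. The overlap test, the region classes, the score test, the reading of steps and the gene-list test were tested on simulated data. With no planted overlap among 15543 regions, 33 overlaps were found (one-sided permutation p 0.542), and of 4662 planted overlaps 4685 were found, random ones included. Of 300 planted gained and 50 planted lost regions, 300 and 50 were recovered, and a planted step of 2.7 came back as 2.7. Alternatives were replicates left out in turn, other overlap rules, the upper part of each list by score, pooled in place of replicate lists, other distances to genes and the replicate number as a block.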

Results

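Ba/F3 is a mouse pro-B cell line that depends on interleukin 3 (IL3) for growth and survival. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for 3 proteins. STAT5A is the transcription factor that the IL3 receptor activates through JAK kinases, LSD1 (encoded by Kdm1a) is a histone demethylase of CoREST complexes, and HDAC3 is the histone deacetylase of NCoR complexes. Cells maintained in 1 ng/mL IL3 were deprived of it for 6 h (without IL3), or deprived for 6 h and then given 10 ng/mL IL3 for 30 min (with IL3). Each protein and condition had 2 biological replicates, 12 libraries in all, and the authors also called regions on the pooled library of each of the 6 groups. Positions are on mm10.

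The replicate lists of STAT5A held 354 and 4513 regions without IL3 and 13574 and 6288 with IL3. Those of LSD1 held 1007 and 15786 without and 6479 and 11570 with IL3, and those of HDAC3 held 1632 and 535 without and 683 and 265 with IL3. Read totals are not given in the sources used here. In every list the scores are whole multiples of 1 step, and if 1 step is 1 read, the inverse of the step gives the depth relative to the shallowest library, LSD1 without IL3 replicate 1. On that reading the other LSD1 libraries had depths of 4.96, 6.11 and 5.67, the STAT5A libraries 2.76 and 4.45 without and 4.05 and 3.02 with IL3, and the HDAC3 libraries 2.68 and 4.12 without and 5.52 and 8.84 with IL3. The 8.84, of replicate 2, exceeds the 8.61 of the pooled list that includes this library, and the pooled list less replicate 1 leaves 3.09. The weakest called regions held 4 to 6 steps, which sets the floor below which binding was not detectable. Both replicate lists held 13.9% of the pooled STAT5A regions with IL3 and 1.61% of those without, 21.3% and 4.65% for LSD1, and 1.08% and 4.96% for HDAC3.

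**Figure D1:**
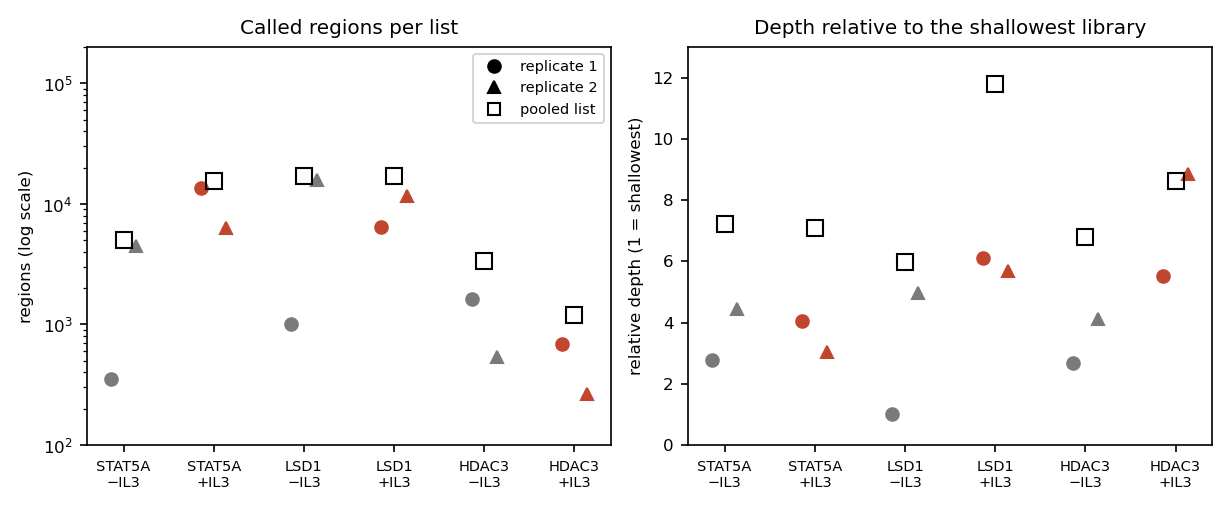
Called regions per list (left, log scale) and depth relative to the shallowest library as read from the score steps (right), with 1 point per replicate, grey without IL3 and red with IL3, and an open square for the pooled list. The STAT5A lists range from 354 to 13574 regions and the HDAC3 lists from 265 to 1632.

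STAT5A without and with IL3 was compared to ask where it binds after the cytokine is given. With IL3, STAT5A regions lay at the genes of the feedback inhibitors of cytokine signalling. Cish had 4 regions within 10 kb of a gene end in each replicate with IL3 against 1 and 1 without, Socs1 had 3 and 2 against 0 and 0, and Socs3 had 3 and 3 against 0 and 1, while Socs2 had 2 and 1 against 0 and 1. Osm, which encodes the cytokine oncostatin M, had 4 and 4 against 0 and 0, and Pim1, which encodes a survival kinase, had 4 and 3 against 0 and 1. Of the BCL2-family survival genes, Mcl1 had 3 and 2 against 0 and 0, and Bcl2l1 had 3 and 0 against 0 and 1. A region inside Bcl2l1 (459.3), more than 10 kb from its ends, was called in both replicates with IL3 and in replicate 2 without. The highest score of the pooled list with IL3, 681.5, was on chromosome 17 at 29395529 to 29395703, between Fgd2 and Pim1 and 95.2 kb from Pim1. Next came a region on chromosome 12 at 77056971 to 77057145, 94734 bp from Max (621.7), and the region 53 bp from the end of Cish, on chromosome 9 at 107296520 to 107296694 (587.5). Without IL3 the 10 highest-scoring STAT5A regions lay near Axin2 (215.8), Pcbp2 (132.0), Pex2, Rpp21, Srm and Ncbp3 and in Arhgef1 (157.1), Cdk8, Cipc and Ift46, and 5 of them were in all 6 pooled lists, whatever the antibody.

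Of the 500 highest-scoring STAT5A regions of each replicate with IL3, 82.8% (replicate 1) and 90.4% (replicate 2) were found in the other replicate with IL3, and 2.80% to 20.6% in a replicate without IL3. A count of 1811 regions was called in both replicates with IL3 and in neither without, and 10 regions the other way round. Among those 10 were regions within 1 kb of an end of Atf6, Tmem223, Nup54 and Xylb, named after their values were seen. The other ways of parting the same 4 lists into pairs gave at most 1069 regions, those called only in the number 2 lists of both conditions, and 3 ways to part the lists are too few for a share under 0.05. In the pooled lists, 1689 of the 15543 regions with IL3 (10.9%) overlapped one without, which leaves 13854 called with IL3 alone and 3354 called without IL3 alone. The replicate lists held 9931 ± 5152 regions with and 2434 ± 2941 without IL3 (mean ± SD, n = 2 each), a log2 ratio of 2.87 with a two-sided exact permutation p of 0.333, the smallest that 2 against 2 allows. The ratio was 1.03 without replicate 1 and 4.71 without replicate 2 of the group without IL3, and the 1811 became 4877 without replicate 1 and 12971 without replicate 2 of the group with IL3. The 10 became 2929 without replicate 1 and 145 without replicate 2 of the group without IL3, and 32 without replicate 1 of the group with IL3.

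LSD1 without and with IL3 was compared to ask if the cytokine moves this demethylase. The 10 highest-scoring regions of each pooled LSD1 list were called in all 4 replicate lists, and 6 were among the 10 in both conditions. The highest score with IL3 lay 61130 bp from Axin2 (408.1), at a region in all 6 pooled lists. Also among the 10 with IL3 were regions in Zfpm1, which encodes the GATA cofactor FOG1 (chromosome 8 at 122315014 to 122315184, score 254.1), and in Smad3 (175.8), both among the 10 with IL3 alone. Others lay near Incenp (225.9), Rpp25 (216.9) and Gpr84 (204.1). Of these 10 regions with IL3, 8 were in all 6 pooled lists, those of STAT5A and HDAC3 included, among them the regions of Zfpm1, Smad3, Incenp and Rpp25. Without IL3, 6 of 10 were, and the 4 others lay near Gpr84, Tigar and Micall1 and in Plin3. In the list of LSD1 and HDAC3 complexes, Gfi1b, whose product recruits LSD1, had its top region 3025 bp from a gene end at 210.5 without IL3 and 3050 bp from it at 75.7 with IL3. In the myeloid and mast cell list, Lyl1 had 149.6 without and 96.3 with IL3, and scores of separate lists are not compared.

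Leaving out replicate 1 without IL3, which had the lowest depth, 87.0% to 97.2% of the 500 highest-scoring regions of an LSD1 list were found in another. The count of LSD1 regions called in both replicates with IL3 and in neither without was 757, and 72 were called the other way round. The number 2 lists of both conditions shared 3573 regions that the number 1 lists lacked. The pooled lists shared 8935 regions, 52.3% of the 17087 with IL3, and 8152 were called with IL3 alone and 7953 without IL3 alone. The replicate lists held 9025 ± 3599.9 regions with and 8397 ± 10450.3 without IL3 (n = 2 each), a log2 ratio of 1.12 with a two-sided exact permutation p of 1. That ratio turned to −0.87 without replicate 1 and was 3.10 without replicate 2 of the group without IL3, and it was 0.70 without replicate 2 of the group with IL3. The 757 became 3119 without replicate 2 of the group without IL3, and 4849 without replicate 1 and 2649 without replicate 2 of the group with IL3. The 72 became 8165 without replicate 1 and 210 without replicate 2 of the group without IL3, and 115 and 220 without replicate 1 or 2 of the group with IL3.

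HDAC3 gave the shortest pooled lists. The highest scores in both conditions lay at 4 regions that were in all 6 pooled lists whatever the antibody. With IL3 they lay 61130 bp from Axin2, in Cdk8, 282089 bp from Pex2 and 24372 bp from Rpp21. The input was not used here, so signal at these 4 regions that does not depend on the antibody was not tested for. After those, the highest-scoring regions with IL3 lay 140094 bp from Tbl1xr1, whose product is itself a subunit of NCoR complexes (68.5), in the ribosomal protein gene Rpl8 (61.5), 209 bp from an end of the erythroid and megakaryocyte factor gene Nfe2 (59.7), 10052 bp from the kinase gene Jak2 (47.4) and 10189 bp from Cish (47.4). The regions near Tbl1xr1 and Jak2 were also in all 6 pooled lists, as were 7 of the 10 highest-scoring with IL3 and all 10 without, and those near Cish and Nfe2 and in Rpl8 were not. The regions near Jak2 and Cish were called in replicate 1 with IL3 and not in replicate 2, and that in Rpl8 was called in replicate 2 and not in replicate 1. HDAC3 was called near Jak2 in both replicates without IL3 too, and near Cish in neither.

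Between 3.00% and 40.6% of the highest-scoring HDAC3 regions of a list were found in another. In both replicates without IL3 and in neither with it, 92 HDAC3 regions were called. The other way round there was 1, on chromosome 5 at 146261106 to 146261363 in Cdk8, beside the region there that is in all 6 pooled lists. The number 1 lists of both conditions shared 197 regions that the number 2 lists lacked. The replicate lists held 474 ± 296 regions with and 1084 ± 776 without IL3 (n = 2 each), a log2 ratio of −1.14 with a two-sided exact permutation p of 0.667. It was −1.94 without replicate 2 and −0.33 without replicate 1 of the group without IL3, and −1.82 without replicate 1 and −0.45 without replicate 2 of the group with IL3. The 92 became 413 without replicate 1 and 1358 without replicate 2 of the group without IL3, and 152 without replicate 1 of the group with IL3, and the 1 gained region became 175 and 398 without replicate 1 or 2 of the group with IL3 and 7 and 2 without replicate 1 or 2 of the group without IL3. Replicate 2 with IL3 stood apart, with 74.2% of its summed score in 1 region.

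**Figure D2:**
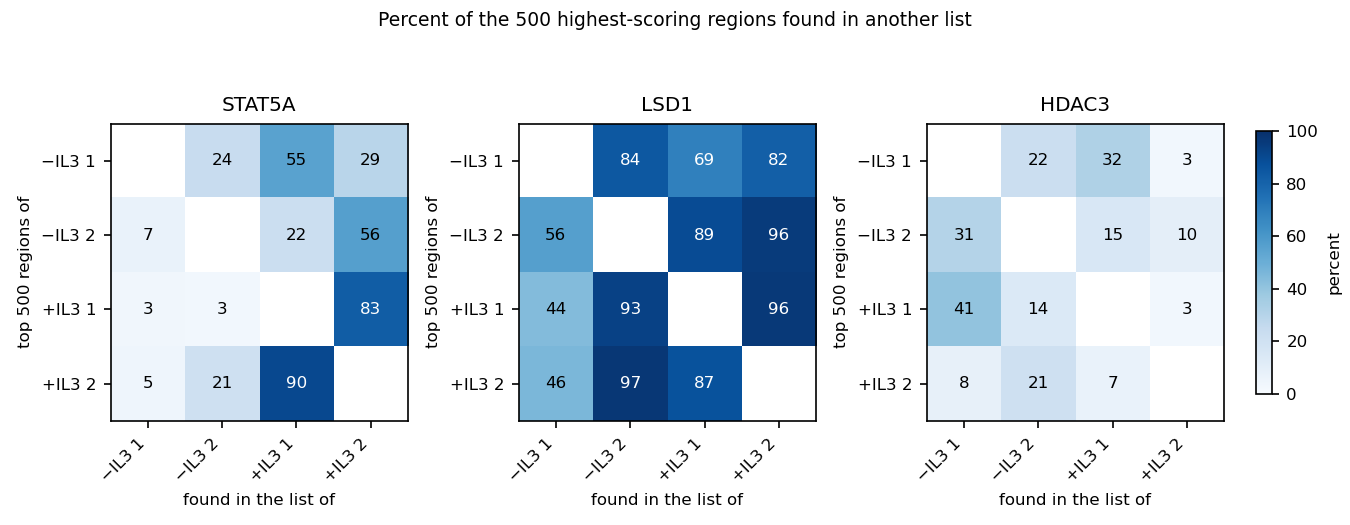
Percent of the 500 highest-scoring regions of each replicate list (vertical; all 352 and 234 regions of STAT5A without IL3 replicate 1 and HDAC3 with IL3 replicate 2) that overlap a region of another list of the same protein (horizontal). STAT5A replicates with IL3 share 82.8% and 90.4% of them with each other, and STAT5A without IL3 replicate 2 shares 56.4% with replicate 2 and 22.4% with replicate 1 with IL3.

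Co-occupancy was measured to ask where LSD1 and HDAC3 meet STAT5A. All 10 of the highest-scoring STAT5A regions called with IL3 alone overlapped an LSD1 region with IL3, and 8 overlapped a pooled HDAC3 region with IL3, of which 6 were called in HDAC3 replicate 1 and 0 in replicate 2. One of these regions lies in Tmprss6, and the others are named by the gene with the nearest end. These are Dcps (450 bp away), Rab44 (2646 bp), Hormad2 (6307 bp), Lrp12 (13812 bp), Adgre1 (13997 bp) and Fgd2 (16080 bp). Farther off are Dusp1 (25560 bp), which encodes a MAP kinase phosphatase, Max (94734 bp) and Tomm20 (166816 bp). Without IL3, 7 of the 10 overlapped an LSD1 region and 3 an HDAC3 region in the pooled lists. At the regions named for Dcps and Dusp1, LSD1 was called in both replicates with IL3 and in neither without. Nearer to Dusp1, 695 bp from a gene end, the pooled LSD1 list without IL3 had another region (45.6). At the regions named for Max, Hormad2 and Dusp1, HDAC3 was called in replicate 1 with IL3 and in neither replicate without.

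With IL3, 5187 of 15543 STAT5A regions (33.4%, 95% interval 32.6 to 34.1) overlapped LSD1 and 709 (4.56%, 4.24 to 4.90) overlapped HDAC3, 132 and 246 times the number at random positions on the same chromosomes. Of the 1208 HDAC3 regions with IL3, 834 (69.0%) overlapped LSD1, 282 times the random number, and 58.7% overlapped STAT5A. By replicate, 75.7% and 19.7% of HDAC3 regions with IL3 overlapped the pooled LSD1 list, and 70.3% and 14.1% the pooled STAT5A list. Without IL3, 2650 of 5043 STAT5A regions (52.5%) overlapped LSD1 and 864 (17.1%) overlapped HDAC3, 208 and 360 times the random number, and 2328 of 3347 HDAC3 regions (69.6%) overlapped LSD1, 287 times. All 3 proteins met in 651 merged regions with and 823 without IL3. For each of these 6 overlaps the one-sided permutation p, raw and adjusted, was 0.000999, the smallest that 1000 placements can give. Placements were not limited to accessible chromatin or expressed genes, so overlap beyond such a shared background was not tested. With the same regions shifted by 10 kb as the control, the multiples were 38.4, 40.5 and 64.2 with and 50, 75.1 and 50.1 without IL3. When regions at gene ends were placed at other gene ends, an alternative added after seeing the data, the multiples with IL3 fell to 21.5, 68.8 and 48.9 and those without to 16.2, 39.1 and 47.5, with the same one-sided permutation p of 0.000999. Leaving out HDAC3 with IL3 replicate 1 left 60.2 and 72.8 for HDAC3 with STAT5A and with LSD1, and leaving out LSD1 replicate 2 raised HDAC3 with LSD1 to 531 with and 847 without IL3 and STAT5A with LSD1 to 445 without. The multiple for STAT5A with HDAC3 was 374 without STAT5A replicate 1 with IL3 and 623 without STAT5A replicate 2 without IL3.

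In the pooled lists, STAT5A regions with the highest scores were those that most often carried HDAC3 with IL3. Regions with HDAC3 had a median score of 44.9 against 23.5 for those without, and regions with LSD1 had 25.6 against 23.5. For both, the two-sided permutation p was 1e-05, the smallest that 100000 resamples can give. In the upper 1555 regions, that is the first of 10 equal parts of the list, 52.2% overlapped LSD1 with IL3 (95% interval 49.7 to 54.6) and 33.3% LSD1 without IL3, and 16.0% overlapped HDAC3 with IL3 (14.3 to 17.9) and 11.1% HDAC3 without IL3. By replicate, HDAC3 with IL3 overlapped 13.8% and 0.579% of this first part, so its pooled share rests mostly on replicate 1. HDAC3 without IL3 was higher in the third part (12.9%) than in the first. In the lowest part 24.1% overlapped LSD1 and 0.515% HDAC3 with IL3. The ratio of medians was 1.09 for LSD1, and between 1.09 and 1.44 with 1 replicate left out, the highest without STAT5A replicate 2. For HDAC3 it was 1.91, and 3.09 without HDAC3 replicate 2 and 2.20 without STAT5A replicate 2. Without HDAC3 replicate 1 it was 1.54, from 33 STAT5A regions with HDAC3 (two-sided permutation p 0.00915). The difference of medians within the pooled list, 2.1 for LSD1 and 21.4 for HDAC3, was 6.4 without LSD1 replicate 2, and 12.8 and 49.1 without HDAC3 replicate 1 or 2. The 2.1 for LSD1 is about 1 score step of this list (2.14). Among regions away from gene ends, an alternative added after seeing the data, the differences were 8.5 and 32.1.

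**Figure D3:**
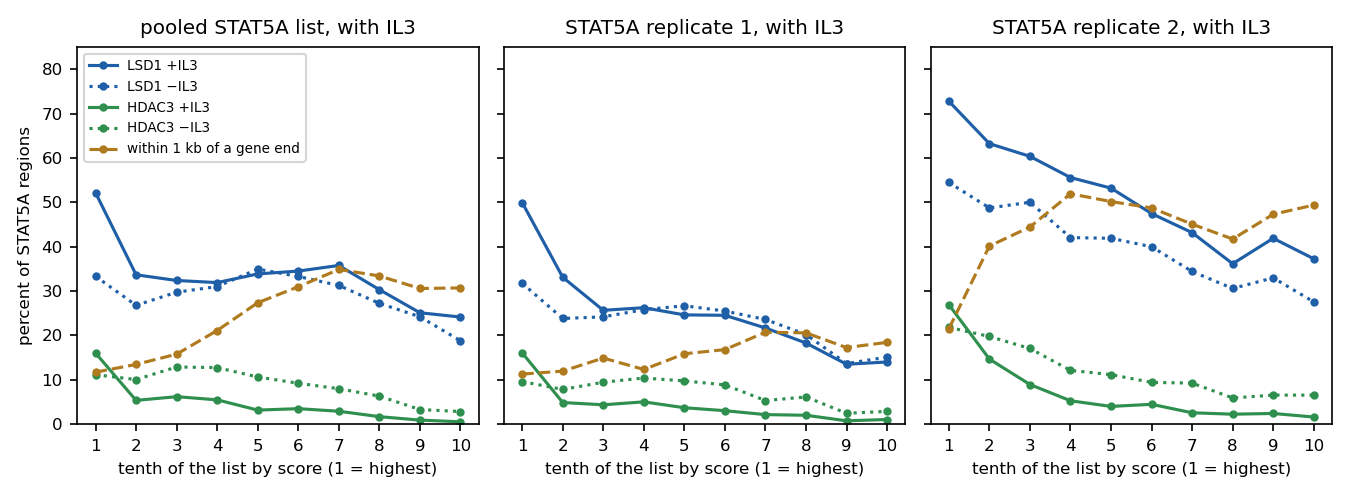
Percent of STAT5A regions with IL3 that overlap LSD1 or HDAC3 of either condition, or lie within 1 kb of a gene end, in 10 equal parts of each list ordered by score, for the pooled list and both replicates. LSD1 with IL3 overlaps 52.2% of the highest-scoring part of the pooled list and 24.1% of the lowest.

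STAT5A regions called with IL3 alone were compared with those called in both conditions (retained). The highest-scoring retained regions lay 53 bp from Cish (587.5), 156694 bp from Ctnnb1 (467.9), inside Bcl2l1, which encodes the survival protein BCL-XL (chromosome 2 at 152789589 to 152789763, 459.3), and 4812 bp from Pim1 (chromosome 17 at 29500837 to 29501011, 452.9). Of the 10 highest-scoring retained regions, 3 and 2 were in replicate 1 and 2 without IL3, and the region near Pim1 was in the pooled list without IL3 and in neither of its replicates. Those in Bcl2l1 and near Pim1 and Ctnnb1 overlapped LSD1 and HDAC3 with IL3, and that at Cish overlapped neither. Of all retained regions 72.5% (1224 of 1689, 95% interval 70.3 to 74.5) overlapped LSD1 with IL3, against 28.6% (3963 of 13854, 27.9 to 29.4) of those called with IL3 alone, with a two-sided Fisher's exact p of 1.53e-267 (adjusted 9.19e-267). HDAC3 with IL3 overlapped 14.4% and 3.36% (two-sided Fisher's exact p 1.19e-66, adjusted 2.39e-66), in which 244 retained regions carried HDAC3. By how the classes were defined, the 207 merged regions in all 6 pooled lists fall among retained regions with LSD1 and HDAC3. Beside the 244 retained regions with HDAC3, these 207 can make up most of them. The HDAC3 difference may thus rest on regions called with every antibody. The comparison was not repeated without them, so it does not show more HDAC3 at the other retained regions. Regions are not independent replicates. The differences were −43.9 and −11.1 percentage points, and the LSD1 difference was −27.9 without LSD1 replicate 2 and −29.2 without STAT5A replicate 1 with IL3, and the HDAC3 difference −1.16 without HDAC3 replicate 1, −7.10 without HDAC3 replicate 2, −20.2 without STAT5A replicate 2 with IL3 and −22.7 without STAT5A replicate 2 without IL3. With gained and retained regions taken from the replicate lists the differences were −28.8 and −19.1. At gene ends they were −29.2 and −2.70, and away from gene ends −51.6 and −21.2, both alternatives added after seeing the data.

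Whether LSD1 itself changed where STAT5A was gained was asked in comparisons chosen after seeing the data. At the 1811 STAT5A regions gained in both replicates, the pooled LSD1 list overlapped 57.8% with and 40.2% without IL3. LSD1 was called with IL3 alone at 424 of them and without IL3 alone at 106, a two-sided exact binomial p of 4.97e-46 (adjusted 1.49e-45). By replicate, the LSD1 lists covered 33.7% and 47.5% of them with IL3 and 3.92% and 37.3% without, and the pooled LSD1 depth on the reading above was 11.8 with and 5.96 without IL3. At the 335 STAT5A regions of both replicates with IL3 that were also in a list without IL3, the pooled LSD1 list overlapped 86.6% with and 80.9% without IL3. LSD1 was called there with IL3 alone at 41 and without IL3 alone at 22 (two-sided exact binomial p 0.0226, adjusted 0.0271). Over all 15543 pooled STAT5A regions with IL3 these numbers were 1903 and 1231 (adjusted two-sided exact binomial p 4.81e-33). From the side of LSD1, 126 of the 1097 LSD1 regions at gained STAT5A regions (11.5%) were themselves called in both replicates with IL3 and in neither without, against 631 of 21458 other LSD1 regions (2.94%), with a two-sided Fisher's exact p of 7.48e-35 (adjusted 1.28e-34). The ratio of these shares was 3.91, and it was 1.39 without LSD1 replicate 1 and 1.75 without replicate 2 of the group with IL3, and 2.16 without replicate 2 of the group without. The difference of 8.55 percentage points was 23.0 without LSD1 replicate 2 of the group without IL3, and at gene ends it was 2.24 with a two-sided Fisher's exact p of 0.174. It was 3.46 (ratio 2.32) with STAT5A regions gained in the pooled lists, and 7.28 (ratio 2.63) against the other LSD1 regions at STAT5A regions with IL3. For HDAC3, 147 of the 1811 regions were called with IL3 alone and 155 without IL3 alone (two-sided exact binomial p 0.687), where the pooled HDAC3 list without IL3 is 2.77 times as long. At the 335 regions the numbers were 18 and 68, and over all 15543 pooled STAT5A regions with IL3 they were 345 and 988 (adjusted two-sided exact binomial p 7.94e-08 and 2.63e-71). The test takes both conditions as equally likely, while the pooled HDAC3 lists hold 1208 regions with and 3347 without IL3. These p-values therefore do not show a change of HDAC3 at STAT5A regions beyond list length. HDAC3 regions called with IL3 alone overlapped STAT5A with IL3 in 48.8% (347 of 711) against 34.9% (994 of 2850) of those called without IL3 alone, with a two-sided Fisher's exact p of 1.27e-11 (adjusted 1.70e-11). That difference of 13.9 percentage points turned to −33.6 without HDAC3 replicate 1 and was 28.3 without HDAC3 replicate 2 of the group with IL3, 27.1 without replicate 1 and 3.62 without replicate 2 of the group without IL3, the last with a two-sided Fisher's exact p of 0.110.

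Position relative to genes was measured as the share of regions with their centre within 1 kb of either end of a protein-coding gene. STAT5A regions gained with IL3 lay mostly away from gene ends, which was not particular to them. Of the pooled STAT5A regions, 54.8% (95% interval 53.4 to 56.2) lay at gene ends without IL3 and 25% (24.3 to 25.7) with IL3, and of the 1811 gained in both replicates 16.7% (15.1 to 18.5). Regions only in the number 1 lists of both conditions had 15.4% (12 of 78), and those only in the number 2 lists 73.2%. Of the pooled regions, 3213 of 5043 without IL3 were in replicate 2 alone, and 9030 of 15543 with IL3 in replicate 1 alone. The pooled fall thus also reflects which replicate the regions came from. LSD1 had 34.4% without and 40.8% with IL3, and HDAC3 26.4% and 23.4%. Random placement gave 3.18% to 3.29%, with a one-sided permutation p of 0.000999 for all 6 lists, the smallest possible. Among the 13 regions called in both replicates the HDAC3 share with IL3 was 7.69% (1 region), too few to show a difference from chance, with a one-sided permutation p of 0.379.

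By replicate, the STAT5A gene-end share was 22.2% and 60.9% without and 16.0% and 44.0% with IL3. The difference between conditions (41.5% ± 27.4 against 30.0% ± 19.8, SD, n = 2 each) was smaller than the spread between replicates (two-sided exact permutation p 0.667). Within replicate numbers 1 and 2 the change with IL3 was −6.16 and −16.8 percentage points, a pairing that this test leaves out. LSD1 gave 33.2% ± 1.62 without and 41.5% ± 1.21 with IL3 (two-sided exact permutation p 0.333, adjusted 0.733 over 11 such comparisons), higher in both replicates with IL3 than in either without. HDAC3 gave 22.5% ± 11.2 and 22.7% ± 9.06 (two-sided exact permutation p 1). Within the pooled STAT5A list with IL3, 34.1% of regions with LSD1 and 20.4% of those without lay at gene ends (two-sided Fisher's exact p 1.44e-74), a difference of 13.7 percentage points that turned to −11.2 for regions called in both replicates, and that was 1.96 without STAT5A replicate 2 and 6.24 without LSD1 replicate 2. For HDAC3 the shares were 16.4% and 25.4% (two-sided Fisher's exact p 1.93e-08), a difference of −9.03 that was −0.74 without HDAC3 replicate 1 (two-sided Fisher's exact p 1), −15.2 without HDAC3 replicate 2 and −25.1 without STAT5A replicate 1.

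**Figure D4:**
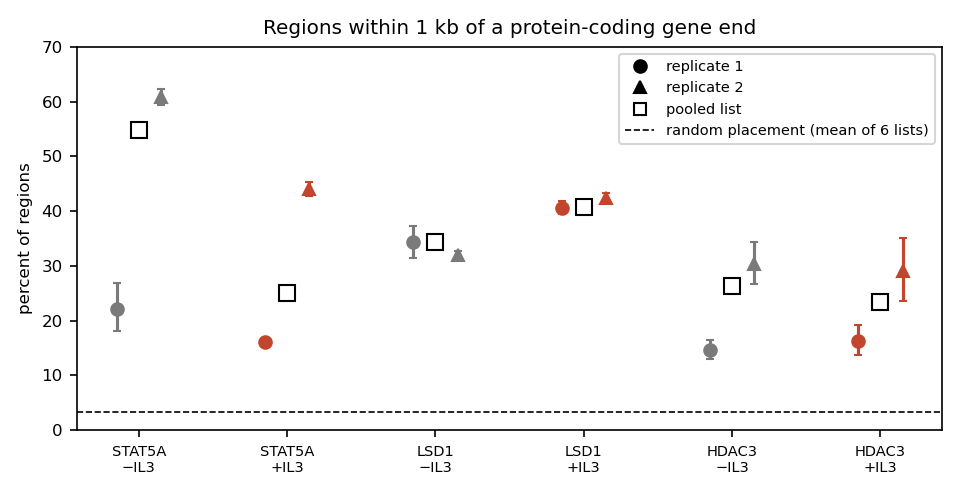
Percent of regions within 1 kb of either end of a protein-coding gene, 1 point per replicate with its 95% Wilson interval, grey without and red with IL3, open squares for pooled lists and a dashed line for random placement. The STAT5A replicates 2 (60.9% and 44.0%) lie above the replicates 1 (22.2% and 16.0%) in both conditions.

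Gene groups were compared with all other protein-coding genes by the share with a pooled region within 10 kb of a gene end. STAT5A with IL3 was near 20 of 22 known STAT5 targets, all but Bcl6 and Ccnd1, and near all 15 immediate early genes, among them Junb (209.4) and Ier3 (200.8). It was near 13 of 15 genes of the IL3 receptor and JAK-STAT pathway, among them Csf2rb (153.8) and Csf2rb2 (143.1), and near 13 of 15 genes of LSD1 and HDAC3 complexes, among them Gps2 (173.0), Hdac1 (147.4) and Rcor1 (138.9). Ribosomal protein genes followed with 55 of 80. Other genes had a region in 37.4% to 37.5%, and the two-sided Fisher's exact p adjusted over 66 tests was 6.44e-06, 6.82e-06, 6.65e-04, 6.65e-04 and 1.25e-06 in that order. The other genes include silent ones, and expression and open promoters were not taken into account. Each of these groups also passed for the pooled LSD1 list with IL3, so passing was not particular to STAT5A.

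The other groups did not pass. Survival and apoptosis genes had a STAT5A region with IL3 at 7 of 10 (two-sided Fisher's exact p 0.0477, adjusted 0.0899), cell cycle genes at 6 of 11, myeloid and mast cell genes at 9 of 16, and B lineage genes at 6 of 16, with none within 10 kb of an end of Ebf1, Pax5 or Il7r. Erythroid and T cell genes had one at 2 of 10, Gata1 and Klf1, and tissue genes of other lineages at 2 of 10, Alb and Myh6. By replicate, STAT5 targets had a region at 20 and 14 of 22 with IL3 and at 1 and 10 without, and ribosomal protein genes at 42 and 34 of 80 with and 3 and 19 without. The same 5 groups passed without IL3, where the pooled STAT5A list was near 10 of 22 STAT5 targets, 8 of 15 immediate early genes, 9 of 15 JAK-STAT pathway genes, 9 of 15 genes of LSD1 and HDAC3 complexes and 28 of 80 ribosomal protein genes (adjusted two-sided Fisher's exact p 0.0379, 0.0224, 0.00516, 0.00516 and 0.0250), and the difference between conditions was not tested. Within 1 kb of a gene end, 2 groups passed with IL3, STAT5 targets and ribosomal protein genes. For regions called in both replicates, the LSD1 and HDAC3 complexes lost their call and survival and apoptosis genes passed. Without replicate 2 with IL3, survival and apoptosis genes and myeloid and mast cell genes passed as well, at 7 of 10 and 10 of 16.

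The stretch of chromosome 17 from Cdkn1a to the far side of Pim1, 440 kb long and chosen after its values were seen, held the region with the highest STAT5A score. STAT5A had 24 and 19 regions there in the replicates with IL3 and 0 and 7 without. LSD1 had 14 and 27 with and 2 and 24 without IL3, and HDAC3 had 6 and 1 with and 7 and 4 without. The 3 highest STAT5A scores with IL3 there lay 2646 bp from Rab44 (546.9), at the top region between Fgd2 and Pim1 (681.5), and 4812 bp from Pim1 (452.9). At all 3, the pooled LSD1 lists of both conditions and the pooled HDAC3 list with IL3 had a region, and the pooled HDAC3 list without IL3 had one at the top region and near Pim1 and one at 29111572 to 29111718 that starts beside the STAT5A region near Rab44. The next scores, 403.8, 275.6, 237.1 and 220, lay at regions that overlapped no pooled HDAC3 region of either condition. Pooled LSD1 overlapped the region of 403.8 in both conditions and that of 220 without IL3 alone. It overlapped those of 275.6 and 237.1 in neither condition.

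**Figure D5:**
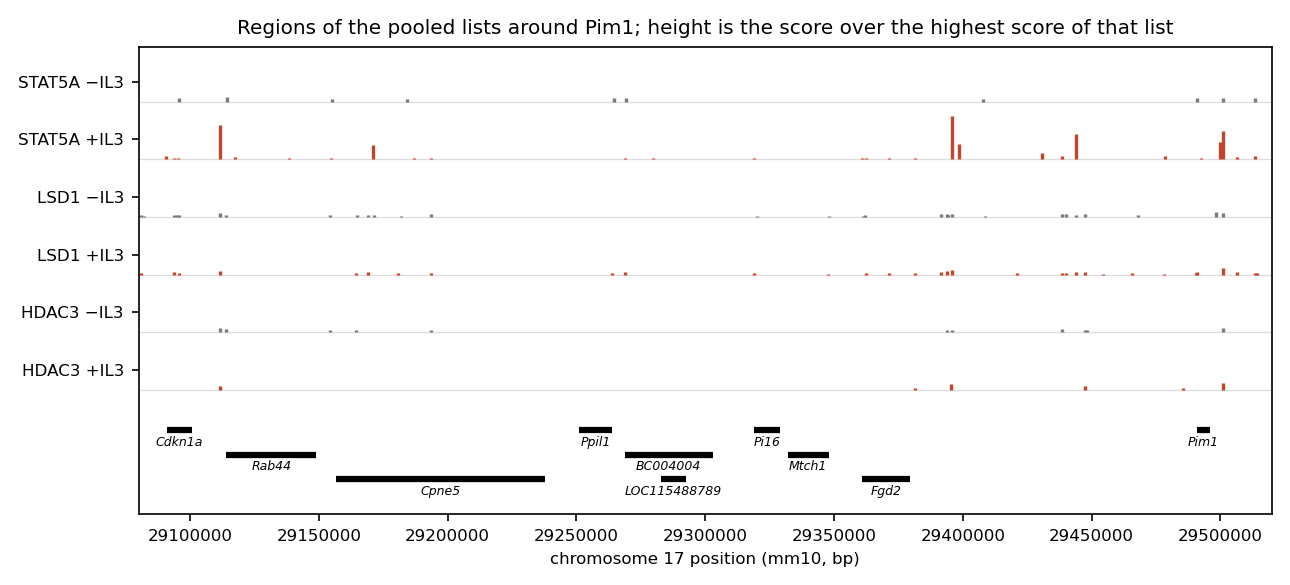
Regions of the 6 pooled lists along 440 kb of chromosome 17 (mm10), grey without and red with IL3, with bar height as the score over the highest score of the same list, so that heights compare within a list only, and protein-coding genes below as black bars. The pooled STAT5A list has 28 regions there with IL3 and 10 without.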

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

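All tests in this part were chosen after the results were seen.

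The change in gene-end share from without to with IL3 was −19.8 percentage points for STAT5A less that for LSD1: both STAT5A replicates with IL3 lay below the same-numbered replicate without, and both LSD1 replicates lay above. The log2 ratio of region numbers was 4.0 higher for STAT5A than for HDAC3, with more STAT5A and fewer HDAC3 regions with IL3 in both same-numbered comparisons. With IL3 labels permuted within each protein, 14 and 4 of 36 arrangements gave a difference as large (two-sided exact permutation p 0.389 and 0.111, smallest possible 0.0556), and this design could not have passed a threshold of 0.05. In HDAC3 with IL3 replicate 2, 31 of 265 regions (11.7%, 95% interval 8.36 to 16.1) lay on sequences outside the assembled chromosomes, which were used in the region counts per list alone, against at most 9 in any other list.

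STAT5A lists with the same replicate number share regions across conditions, and HDAC3 lists do so in part. Of the 500 highest-scoring regions of STAT5A without IL3 replicate 2, 56.4% were in replicate 2 and 22.4% in replicate 1 with IL3, a difference of 34.0 percentage points towards the list that is shorter and has the lower depth, which argues against list length and depth for STAT5A. For HDAC3 these cannot be told apart from the number: regions of replicate 2 without IL3 were found in replicate 2 less often than in the longer replicate 1 with IL3 (9.60% against 15.4%, −5.8 points), but those of replicate 2 with IL3 were found more often in the shorter replicate 2 without (20.9% against 8.12%). A preparation shared by libraries with the same number may contribute: in 4 of 4 comparisons of STAT5A and HDAC3 the number 2 list lay at gene ends more often than the number 1 list, while LSD1 had 34.3% (number 1) and 32.0% without and 40.6% and 42.3% with IL3. The labels give no batch, and no biological explanation was tested.

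The HDAC3 list of replicate 2 with IL3 stands apart, with 74.2% of its summed score in 1 region on chromosome 2 at 98667061 to 98667213. Repeated reads kept in this list are a candidate explanation: that region held 147 times the score steps that 2 per base of its width allow, and no other list exceeded 0.930 times. HDAC3 occupancy of the region could not be judged from the pooled list, which had no region called there. Beyond replicate 1 the pooled list has a depth of 3.09, against 8.84 for replicate 2, so it does not carry all steps of this library. Counting the list of replicate 2, 2 lists had a region there. It stays open which of the other regions of the replicate 2 list are affected.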

How the results depend on the processing

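Of 214 alternatives to 27 results, 179 kept direction and side of the threshold or stayed within 1.5 times the count, 5 lost their call, 27 moved and 3 reversed. For region numbers direction alone was judged, whatever the size of the change. The 179 also include the replicate block for gained and lost counts, which cannot change them. All 60 alternatives for the 6 overlaps stayed above their random or shifted controls, with multiples from 16.2 to 3550. Direction and threshold were kept by all 22 for the LSD1 and HDAC3 shares of gained against retained STAT5A regions and all 12 for STAT5A scores. None of these 22 left out the regions in all 6 pooled lists, on which the HDAC3 difference may rest. Alternatives for the comparisons added after seeing the data were themselves added then. The cause was not tested for any change below.

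With pooled in place of replicate lists, gained and lost counts moved to 13854 and 3354 for STAT5A, 8152 and 7953 for LSD1, and 711 and 2850 for HDAC3. In the upper part of each list by score, 440 LSD1 regions were gained. Without 1 replicate in turn, gained counts ranged from 1861 to 12971 (STAT5A), 780 to 4849 (LSD1) and 2 to 398 (HDAC3), and lost counts from 15 to 2929, 115 to 8165 and 93 to 1358. The log2 ratio of LSD1 region numbers ranged from −0.87, without LSD1 replicate 1 without IL3, to 3.10.

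For regions called in both replicates, the gene-end share of HDAC3 with IL3 was 7.69% (1 of 13 regions) and not past the threshold, the gene-end difference between STAT5A regions with and without LSD1 reversed to −11.2 percentage points, and that with and without HDAC3 was −5.78 and not past the threshold. The last ranged from −25.1 to −0.74 with 1 replicate left out, where HDAC3 with IL3 replicate 1 ended the call. The HDAC3 difference in STAT5A overlap between regions called with and without IL3 alone ranged from −33.6, reversed without that same library, to 28.3. The LSD1 difference at STAT5A gained regions was 2.24 at gene ends alone, not past the threshold. Within 1 kb of a gene end, 2 gene lists passed for STAT5A.

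With the number as a replicate block, the log2 ratios of region numbers were 2.87 (exact sign-flip p 0.5), 1.12 (exact p 1) and −1.14 (exact p 0.5) for STAT5A, LSD1 and HDAC3, two-sided, where 0.5 is the smallest possible, and gained and lost counts are identical by construction. The 5 motif results and their alternatives were not run. Absence from the lists of 354 and 1007 regions shows little, and whether depth made them short was not tested.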

Other observations

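All tests of explanations in this part were chosen after the results were seen.

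LSD1 lay near 14 of 15 genes of LSD1 and HDAC3 complexes in each condition (adjusted two-sided Fisher's exact p 4.46e-04 without and 0.00104 with IL3), at 4 and 14 by replicate without and 11 and 10 with IL3. It was near 13 of 16 myeloid and mast cell genes without IL3 (adjusted two-sided Fisher's exact p 0.00999) and 11 of 16 with IL3 (adjusted 0.134, Fisher's exact), among them Lyl1 and Runx1, at 2 and 12 by replicate without and 9 and 10 with IL3. It was near all 15 genes of the IL3 receptor and JAK-STAT pathway in each, and near 14 and 15 of 15 immediate early genes without and with IL3. STAT5 targets had an LSD1 region at 18 of 22 without and 16 of 22 with IL3, and ribosomal protein genes at 46 and 57 of 80. Of the tissue genes of other lineages, LSD1 was near 1 of 10 in each condition, below the 43.4% and 46.5% of other genes without and with IL3 (adjusted 0.0922 and 0.0478, Fisher's exact). LSD1 was near 8 of 16 B lineage genes without and 9 of 16 with IL3, which did not pass. The B lineage factor genes Ebf1 and Pax5 and the receptor gene Il7r had no region of any of the 3 proteins within 10 kb of an end in a pooled list.

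HDAC3 with IL3 was near 9 of 22 STAT5 targets against 3.72% of other genes (adjusted two-sided Fisher's exact p 1.52e-06), among them Pim1 (40.4), Id1 (38.6), Cish (35.1) and Osm (26.3). By replicate this rests on 1 library: 10 of the 22 had a region in replicate 1 and 0 in replicate 2, while replicate 2 had regions at 11 of 80 ribosomal protein genes and replicate 1 at 0. Without IL3 HDAC3 was near 5 of 22 STAT5 targets (adjusted 0.116, Fisher's exact), 7 and 3 by replicate, and near 9 of 16 myeloid and mast cell genes (adjusted 7.35e-05, Fisher's exact; 6 and 2 by replicate) and 6 of 10 survival and apoptosis genes (adjusted 7.06e-04, Fisher's exact), of which replicate 1 had 4 and replicate 2 had 0. With IL3 these lists had 3 of 16 (adjusted 0.0411, Fisher's exact; 3 and 0 by replicate) and 4 of 10 (adjusted 0.00110, Fisher's exact; 2 and 1 by replicate). The difference between conditions was not tested. Of all merged regions, 207 (0.575%) were in all 6 pooled lists, among them those near Axin2, Pex2 and Rpp21 and in Cdk8, which were in neither number 1 list of STAT5A.

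LSD1 regions appear with IL3 at regions that STAT5A gains: among the 1005 highest-scoring regions of each list, both LSD1 lists with IL3 held a higher share of STAT5A gained regions (19.9% and 19.1%) than both without (7.06% and 11.9%), by at least 7.16 percentage points. The list of replicate 1 without IL3 entered whole, so its share cannot be told apart from list length. Replicate 2 without IL3 had the longest list (15783 regions), and its lower share argues against list length for that list. Replicate number is argued against by the shares within number 2, 19.1% with and 11.9% without IL3. Within number 1 the share was also higher with IL3, but there the list without IL3 entered whole and had the lowest depth. Depth cannot be told apart from IL3, since both libraries with IL3 were deeper, by at least 1.14 times. Recovery of STAT5A-bound DNA by any antibody cannot be told apart from LSD1 arriving, since HDAC3 gave −11.5 points in this test: replicate 1 with IL3 was higher (35.5% against 13.2% in both lists without) and replicate 2 lower (1.71%). LSD1 may be recruited with STAT5A, or depth or such recovery may give the pattern, and these data do not decide.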
